A study of Mus musculus with 4 samples.

How the data were processed

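Poly(A)-selected, strand-specific RNA-seq libraries were made from 4 mouse mammary tumour samples, 2 of Control-PyMT and 2 of MYC-PyMT. Per the labels' protocols, tumours were ground in liquid nitrogen, 500 ng of total RNA went into each TruSeq preparation with 8 PCR cycles, and RNA integrity numbers ran from 3.3 to 9.6. The labels do not tie those numbers to samples, so RNA quality per library was not available for the comparison. Per the submitters' processing notes, reads were aligned with HISAT2 to mouse mm10 (GRCm38.p5) and DESeq2 was used. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be shared.

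The deposited table holds scaled counts (a signal that is never negative, not scaled to library total and not divided by gene length) for 20555 genes, 1 column per sample. Every value in all 4 columns was a whole multiple of what 1 read is worth in that library, within a tolerance of 0.001 reads (100% of values), so the authors' values are whole read counts divided by a size factor, and the reads were recovered. One read was worth 0.935 and 0.849 scaled counts in Control-PyMT replicates 1 and 2, and 1.01 and 1.10 in MYC-PyMT replicates 1 and 2. Totals were 32245080 and 32879311 reads in Control-PyMT and 34190913 and 31783846 in MYC-PyMT. The most abundant gene took 1.15% to 1.60% of a library. A chi-square of the recovered reads between replicates, per degree of freedom, was 61.2 in Control-PyMT and 44.7 in MYC-PyMT, so replicates differed by more than counting noise. Of the gene IDs, 20463 were found in GENCODE mouse release 21, which gave coordinates, gene types, transcript lengths and GC content, and 92 were not. For 23 genes whose symbols had been turned into spreadsheet dates the symbol was taken by ID, and 14 entries shared a symbol with another and were kept apart by ID.

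Because the values are scaled, the test was limma (lmFit and eBayes with a variance trend) on log2(value + 1), two-sided, over genes with a value of at least 10 in at least 2 libraries, 16725 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, which understates changes of low genes. A fold against a group without reads was computed against a floor of 3 reads per library, which is 3.16 scaled counts as the MYC-PyMT mean. With 1 to 3 reads the fold is the ratio of means with an exact 95% counting interval. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. An exact test of 2 against 2 cannot go below p = 0.33, so no single-gene exact test was used. Fitting 4 libraries leaves the spread to be shared across genes.

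The 33 gene lists, written from memory of common markers, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the 33 lists, and again with an estimated correlation and with fry. Members under the level filter or without a match were left out. Ly6g, Mpo, Ifng, Ucp1, mt-Nd4l, mt-Atp8, Mmp1a and 3 histone genes were not analysed here, and Vegfd was matched as Figf. Named genes were Myc, S100a8 and S100a9; the 12 largest changes in each direction among called genes with a mean of at least 50 in the higher group and no overlap between groups, passing over Gm-numbered, Rik and bare identifiers; and the members with the smallest p, 4 of each list past the test and 2 of each other list. Treating clone names as bare identifiers was settled after the values were seen. This gave 115 names, and other genes were chosen after their values were seen.

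The procedure was tested on simulated counts drawn for the same genes and library sizes, with 200 genes changed. Over 16725 genes limma recovered 8% of genes changed 1.5-fold, 44% of those changed 2-fold, 92% of those changed 4-fold and 92% of those changed 8-fold, and called 8 unchanged genes. A list of 30 genes raised 1.5-fold gave a camera p of 8.65e-08 and a list of 30 unchanged genes 0.286. Simulated genes were drawn independently, whereas estimated correlations in the data were 0.12 for MYC targets and 0.46 for ribosomal proteins. Far fewer genes changed than the 8010 called in the data. The simulation therefore does not show how often camera calls unchanged lists of correlated genes.

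Alternatives were pseudocounts of 0.5 and 5, no level filter or one of 50, TMM and upper-quartile scaling, no variance trend, the replicate number as a block, leaving out each library, an adjusted p under 0.10, lists without shared genes, and edgeR's quasi-likelihood test and DESeq2 on the recovered reads. The latter called 7925 and 7293 genes. Removing each library's trend with transcript length (lowess), alone or with GC content, was added after the data had been seen, as were 9 further gene lists. Such a removal also takes out any real change shared by genes of similar length. Replicate numbers in the labels mark no stated litter, batch or day, and the labels give no batch. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.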

Results

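RNA was sequenced from bulk mammary tumours of mice carrying PyMT, the middle T antigen of polyoma virus, which drives mammary tumours. The 4 libraries fell into 2 groups of 2. Control-PyMT is labelled with the PyMT genotype alone. In MYC-PyMT, a Cre recombinase under S100a8, a gene that neutrophils express strongly, was combined with a MYC allele at Rosa26 behind a stop cassette that Cre removes. The series asks how MYC expression affects PyMT tumours. The deposited values are scaled counts, from which whole reads were recovered: 32245080 and 32879311 for Control-PyMT replicates 1 and 2, and 34190913 and 31783846 for MYC-PyMT replicates 1 and 2. Group values are given as the mean ± SD in scaled counts (n = 2 each). Nothing in the labels says that the 2 libraries of a group came from different mice, so the p-values measure the spread between these libraries, which may be technical.

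MYC-PyMT tumours had higher levels of genes for ribosome building, cell division and mitochondrial respiration, and lower levels of interferon response, T and NK cell and antigen presentation genes, by camera at its preset correlation. With an estimated correlation these list calls were lost (adjusted p = 0.643 to 0.770). There camera has only the residual degrees of freedom of 4 libraries, so hardly any list could pass. The loss therefore does not show whether correlated members made these calls. Srm, which makes spermidine, rose from 1257 ± 226 to 8990.3 ± 486 scaled counts, and the nucleolar protein gene Nop56 rose from 3189 ± 406 to 17877 ± 1992. H2-Aa, an MHC class II chain, fell from 7710 ± 261 to 719 ± 28.1. Pgr, the progesterone receptor, fell from 1697 ± 73.4 to 7.18 ± 5.50, and Foxa1, a luminal transcription factor, from 1182 ± 325 to 34.7 ± 14.9. Ido1, the interferon-inducible enzyme that degrades tryptophan, had 1997 and 1796 scaled counts in Control-PyMT and no read in either MYC-PyMT library.

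The mouse Myc gene (ENSMUSG00000022346.14, chromosome 15, 61985391 to 61990374, GRCm38) stood at 1832 and 2820 scaled counts in Control-PyMT replicates 1 and 2, and at 3215 and 2815 in MYC-PyMT replicates 1 and 2. The log2 change was 0.40 (SE 0.23, limma adjusted p = 0.172), which did not pass the test. Without Control-PyMT replicate 2 it was 0.72. That rise rested on Control-PyMT replicate 1 alone, since Control-PyMT replicate 2, at 2820, lay between the MYC-PyMT libraries. The labels do not give the species of the MYC transgene, so these values need not include its reads. S100a9 (ENSMUSG00000056071.12, chromosome 3, 90692632 to 90695721), whose product pairs with that of S100a8 in neutrophil granulocytes, rose from 384 ± 254 to 1027 ± 201, a log2 change of 1.58 (SE 0.40, adjusted p = 0.00925). That call ended without Control-PyMT replicate 2 (log2 0.85, adjusted p = 0.0719), without the variance trend (0.0536) and after removal of the transcript length trend (log2 0.85, adjusted p = 0.0803) or of the length and GC trends (0.82, 0.0740). S100a8 (ENSMUSG00000056054.9, chromosome 3, 90668978 to 90670035) gave 2338 and 639 scaled counts in Control-PyMT and 1564 and 2524 in MYC-PyMT. Its log2 change of 0.70 did not pass (SE 0.49, adjusted p = 0.260). The change in S100a8 was 1.64 without Control-PyMT replicate 1 (adjusted p = 0.0374), 1.05 without MYC-PyMT replicate 1 (0.00547) and -0.23 without Control-PyMT replicate 2 (0.617). It was -0.04 once the length trend was removed (0.945). Removing that trend would also take out a real change shared by genes of similar length. It therefore does not decide whether the changes of S100a8 and S100a9 are technical.

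Of 16725 genes tested, 8010 changed by limma at a Benjamini-Hochberg adjusted p under 0.05, with 3892 higher and 4118 lower in MYC-PyMT. Changes of at least 2-fold on the log2 scale were found for 2404 of the higher and 3060 of the lower genes, and of at least 16-fold for 55 and 290. The groups did not overlap for 75.7% of tested genes, where chance gives 33.3%. Across genes, Pearson's correlation of log2 values was 0.981 between the Control-PyMT libraries, 0.987 between the MYC-PyMT libraries and 0.889 to 0.895 between groups. The first principal component held 87.2% of the variance and separated the groups. Leaving out Control-PyMT replicate 2 left 5236 changed genes, 2573 of them lower, and leaving out Control-PyMT replicate 1 left 2703 lower genes.

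**Figure D1:**
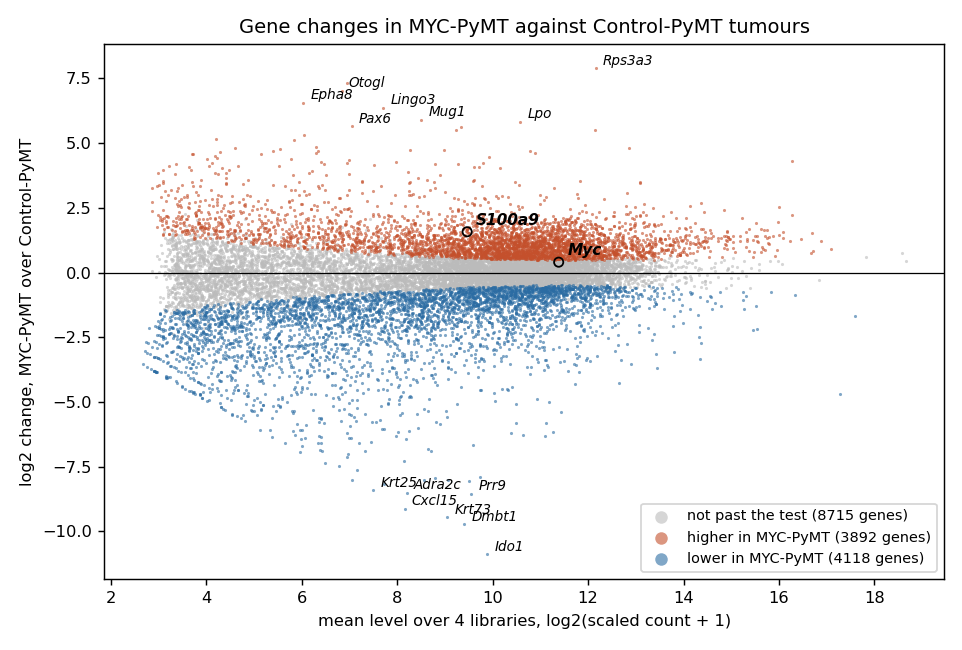
Log2 change in MYC-PyMT over Control-PyMT against the mean level over 4 libraries, log2(scaled count + 1), 1 point per tested gene. Orange marks 3892 genes higher and blue 4118 genes lower by limma, and italic names mark 7 genes per direction from the largest changes; circles mark Myc, at 0.40, and S100a9, at 1.58.

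Among the largest rises was Rps3a3 (chromosome 13, 108670603 to 108671397), from 37.7 ± 8.86 to 9083 ± 341 scaled counts (log2 7.89, SE 0.23, limma adjusted p = 3.22e-07). It is annotated as a processed pseudogene, so its reads may be split with copies of the ribosomal protein gene it derives from, and its value is uncertain. Utf1, a chromatin factor of embryonic stem cells, rose from 24.8 ± 3.35 to 1274 ± 24.3 (log2 5.63), and Lingo3 from 4.76 ± 4.08 to 412 ± 24.2 (log2 6.37). Epha8, an ephrin receptor, had 1 read in the Control-PyMT libraries together and 245 in MYC-PyMT, a 302-fold difference with an exact 95% counting interval of 53.8 to 11992. Otogl, with 2 and 435 reads, was 265-fold higher (73.0 to 2197). Gmnc, a regulator of multiciliated cells, rose from 2.76 ± 2.71 to 128 ± 5.72, and Amn, a partner of the vitamin B12 receptor cubilin, from 4.04 ± 0.90 to 152 ± 63.7. The other large rises differed between the MYC-PyMT libraries. Lpo, the lactoperoxidase of milk and saliva, rose from 43.5 ± 15.3 to 4760 in replicate 1 and 1267 in replicate 2. Pip, a secreted prolactin-inducible protein, rose from 295 and 105 in Control-PyMT to 12807 and 4980.4. Mug1, a protease inhibitor of plasma, rose from 10.4 ± 8.10 to 1113 and 312. Pax6, a transcription factor of eye development, rose from 5.10 ± 6.01 to 122 and 393. Lin28b, which blocks maturation of let-7 microRNAs, had 3 reads in Control-PyMT and 205 in MYC-PyMT, 81.7-fold more (27.6 to 399), with 33.2 and 189 scaled counts in MYC-PyMT replicates 1 and 2. Its call ended without Control-PyMT replicate 2 (log2 4.81, adjusted p = 0.0523).

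Ido1 (chromosome 8, 24584136 to 24597009) headed the falls. With no read in MYC-PyMT it was at least 601-fold lower, against a floor of 3 reads per library (log2 -10.89 on the scale of scaled counts plus 1, SE 0.36, limma adjusted p = 4.79e-07). On the same floor, the chemokine gene Cxcl15 was at least 180-fold lower, the hair inner root sheath keratin gene Krt25 at least 113-fold and the connexin gene Gjc3 at least 82.9-fold. Krt73, another inner root sheath keratin, fell from 1053 ± 413 scaled counts to a single read over both libraries. Likewise 1 read remained of Dmbt1, a secreted scavenger receptor, from 1355 ± 819, of Adra2c, an adrenergic receptor, from 585 ± 393, and of Cyp3a57, a cytochrome P450, from 417 ± 18.3. Counting intervals of the fold were 344 to 75720 for Krt73, 442 to 97407 for Dmbt1, 208 to 45942 for Adra2c and 136 to 30025 for Cyp3a57. Fgb, the fibrinogen beta chain, fell from 748 ± 522, kept 3 reads and was 467-fold lower (159 to 2266). Amtn, an enamel matrix protein, fell from 1436 ± 1003 to 4.12 ± 2.72, Prr9 from 1497 ± 1313 to 4.40 ± 6.22, and the epidermal gene Rptn from 1069 ± 1072 to 2.15 ± 1.62.

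Of 33 gene lists, camera called 6 higher and 6 lower in MYC-PyMT at its preset correlation. No list passed with an estimated correlation, where 1 list, T and NK cell markers, had an unadjusted p under 0.05, and fry, which tests whether a list moved on balance one way, passed 12 lists, 9 of them in common with camera. Beside each call, the p with an estimated correlation is given. With so few libraries hardly any list could pass that version, so its failure does not decide about a call.

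All 47 MYC target genes rose, as did all 47 adjusted over the list alone, with a median log2 change of 1.72 (camera adjusted p = 3.69e-17, and adjusted p = 0.643 with an estimated correlation). With upper-quartile scaling 46 rose. Besides Srm (log2 2.85) and Nop56 (2.49), the folate carrier gene Slc19a1 rose from 460.1 ± 82.0 to 3617 ± 6.14 and the nucleolar gene Nolc1 from 2470 ± 101 to 12513 ± 504. All 30 cell cycle genes rose, over all genes and adjusted over the list alone (median 1.56, adjusted p = 1.01e-11, and adjusted p = 0.691 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, rose from 1329 ± 87.9 to 5727 ± 422, Birc5, the gene for survivin, from 1364 ± 205 to 5367 ± 187, the mitotic kinase gene Aurkb from 582 ± 31.5 to 2165 ± 123, and Ube2c, a ubiquitin-conjugating enzyme of mitosis, from 1210.4 ± 44.6 to 4418 ± 281. All 35 cytosolic ribosomal protein genes rose by both adjustments (median 1.31, adjusted p = 1.28e-11, and adjusted p = 0.741 with an estimated correlation). Rpl8 rose from 23811 ± 25.8 to 76952 ± 8683, and Rps23, Rpl37 and Rpl18 by 1.58, 1.30 and 1.40 on the log2 scale. Short transcripts tended to be higher in MYC-PyMT. Spearman's correlation of the change with transcript length was -0.22 across genes, which are not independent replicates. The eighth of genes with the shortest transcripts had a median log2 change of 0.52. Libraries of the same group also differed along length. For replicate 2 minus replicate 1 the correlation was -0.145 in MYC-PyMT and 0.095 in Control-PyMT. With the length trend removed, the mean log2 difference from all genes moved from 1.88 to 1.86 for MYC targets, from 1.70 to 1.76 for cell cycle genes and from 1.49 to 1.19 for ribosomal protein genes.

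Oxidative phosphorylation genes rose in 23 of 26 cases, over all genes and adjusted over the list alone (median 1.02, camera adjusted p = 3.94e-07, and adjusted p = 0.770 with an estimated correlation), with 22 under upper-quartile scaling. Cyc1, a subunit of respiratory complex III, rose from 3337 ± 122 to 9761 ± 996, cytochrome c (Cycs) from 1775 ± 429 to 5457 ± 978, and Atp5o and Uqcrc1 by 1.53 and 1.24 on the log2 scale. Of 18 glycolysis genes 11 rose and 2 fell, also adjusted over the list alone (median 0.94, adjusted p = 0.0396, and adjusted p = 0.907 with an estimated correlation). Eno1 rose from 11690.3 ± 237 to 36316 ± 4203, Hk2 from 769 ± 54.1 to 2171 ± 281 and Gapdh from 13258 ± 54.5 to 33409 ± 5376. Hk1 and Aldoc, an aldolase best known from brain, fell, with log2 changes of -1.18 and -2.59. Pgk1 rose from 3453 ± 1401 to 10464 ± 2896, a call that ended without Control-PyMT replicate 2 (log2 1.21, adjusted p = 0.0508). The glycolysis call ended without Control-PyMT replicate 1, Control-PyMT replicate 2 or MYC-PyMT replicate 2. The list's mean log2 difference from all genes, 0.70, was then 0.72, 0.68 and 0.52. The call also ended with a level filter of 50 (0.64, camera adjusted p = 0.0509) and by fry (0.144).

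Interferon gamma response genes fell in 20 of 21 cases and type I interferon response genes in 19 of 20, with the same counts adjusted over the list alone. Camera gave adjusted p = 7.90e-10 and 9.71e-09, and adjusted p = 0.643 and 0.691 with an estimated correlation, at medians of -2.48 and -2.40. Iigp1, an interferon-inducible GTPase, fell from 4072 ± 545 to 401 ± 103, Igtp from 1825 ± 7.07 to 227 ± 23.0, and the immunoproteasome subunit gene Psmb8 from 3491 ± 484 to 559 ± 62.3. Oasl2, of the oligoadenylate synthetase family, fell from 3641 ± 225 to 339 ± 92.4, Oas2 from 1537 ± 111 to 143 ± 34.9, the nucleic acid sensor gene Zbp1 from 2082 ± 215 to 216 ± 59.5 and Ifit3 from 2589 ± 233 to 351 ± 67.2. Ptprc, a marker of leukocytes in general that was chosen after its values were seen, fell from 1272 ± 87.7 to 597 ± 83.2, a log2 change of -1.09.

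T and NK cell markers fell in 17 of 20 measured cases, also adjusted over the list alone (median -2.76, camera adjusted p = 2.14e-06, and adjusted p = 0.643 with an estimated correlation). Gzma, a granzyme of cytotoxic cells, dropped from 198 reads to 3 (56.2-fold, interval 19.0 to 275). Cd8a fell from 85.4 ± 10.2 to 4.21 ± 0.26 scaled counts, Cd3g from 65.2 ± 6.95 to 4.21 ± 0.26 and Nkg7 from 73.4 ± 0.67 to 8.28 ± 3.94. Cd4, which macrophage-lineage and dendritic cells can also express, rose by 1.64 on the log2 scale. Dendritic cell and MHC class II genes fell in 10 of 14 cases and 11 adjusted over the list alone (median -2.34, adjusted p = 1.23e-05, and adjusted p = 0.643 with an estimated correlation). Cd74, the invariant chain, fell from 14007 ± 4470.2 to 1172 ± 122, H2-Eb1 from 6126 ± 458 to 523 ± 21.7 and H2-Ab1 from 6137 ± 919 to 870.0 ± 171.

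Luminal epithelial markers fell in 12 of 20 cases with 8 not past the test; adjusted over the list alone, 13 fell and 1 rose (median -0.60, camera adjusted p = 0.00223, and adjusted p = 0.643 with an estimated correlation). The estrogen receptor gene Esr1 fell from 785 ± 12.7 to 113 ± 17.4 and Kit, a receptor of luminal progenitors, from 9694 ± 501 to 2430.5 ± 730. Krt8 and Epcam, pan-luminal genes, had log2 changes of -0.16 and -0.32 that did not pass (adjusted p = 0.568 and 0.198). Keratinocyte and hair genes fell in 9 of 10 measured cases, also adjusted over the list alone, while Sbsn rose (median -2.63, adjusted p = 0.00171, and adjusted p = 0.907 with an estimated correlation). Krt27, like Krt25 a keratin of the hair root sheath, went from 697 reads to 3 (203-fold, interval 69.1 to 985). Krt1 and Krt10, keratins of the upper epidermis, fell from 514 ± 374 to 5.31 ± 1.82 and from 528 ± 150 to 121 ± 20.9. By fry this list did not pass (0.0610).

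Neutrophil markers rose in 11 of 25 cases, fell in 3 and did not pass in 11, with the same counts adjusted over the list alone (median 0.94, camera adjusted p = 0.0436, and adjusted p = 0.907 with an estimated correlation). Under TMM or upper-quartile scaling 10 rose. Prtn3, proteinase 3, rose from 185 ± 29.0 to 1395 ± 409, and Ngp, a granule protein of immature neutrophils, from 3.99 ± 0.36 to 85.3 ± 5.30. Padi4, an arginine deiminase, rose from 291 ± 42.4 to 884 ± 146 and Wfdc21 from 22.8 ± 11.0 to 122 ± 8.31. The members that fell were Ltf, Hcar2 and Lcn2, and the first and last of these are also made by mammary epithelium. Csf3r and Cxcr2, receptors of neutrophils, had log2 changes of -0.36 and -0.30 (adjusted p = 0.346 and 0.642). The list call ended without Control-PyMT replicate 2 (mean log2 difference from all genes 0.65, adjusted p = 0.370, against 1.38 without Control-PyMT replicate 1), with a level filter of 50 (0.224) and by fry (0.195). It also ended with the length trend (0.108) or the length and GC trends (0.127) removed, where the mean log2 difference from all genes was 0.74 and 0.75. The former is 73.4% of the uncorrected value.

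**Figure D2:**
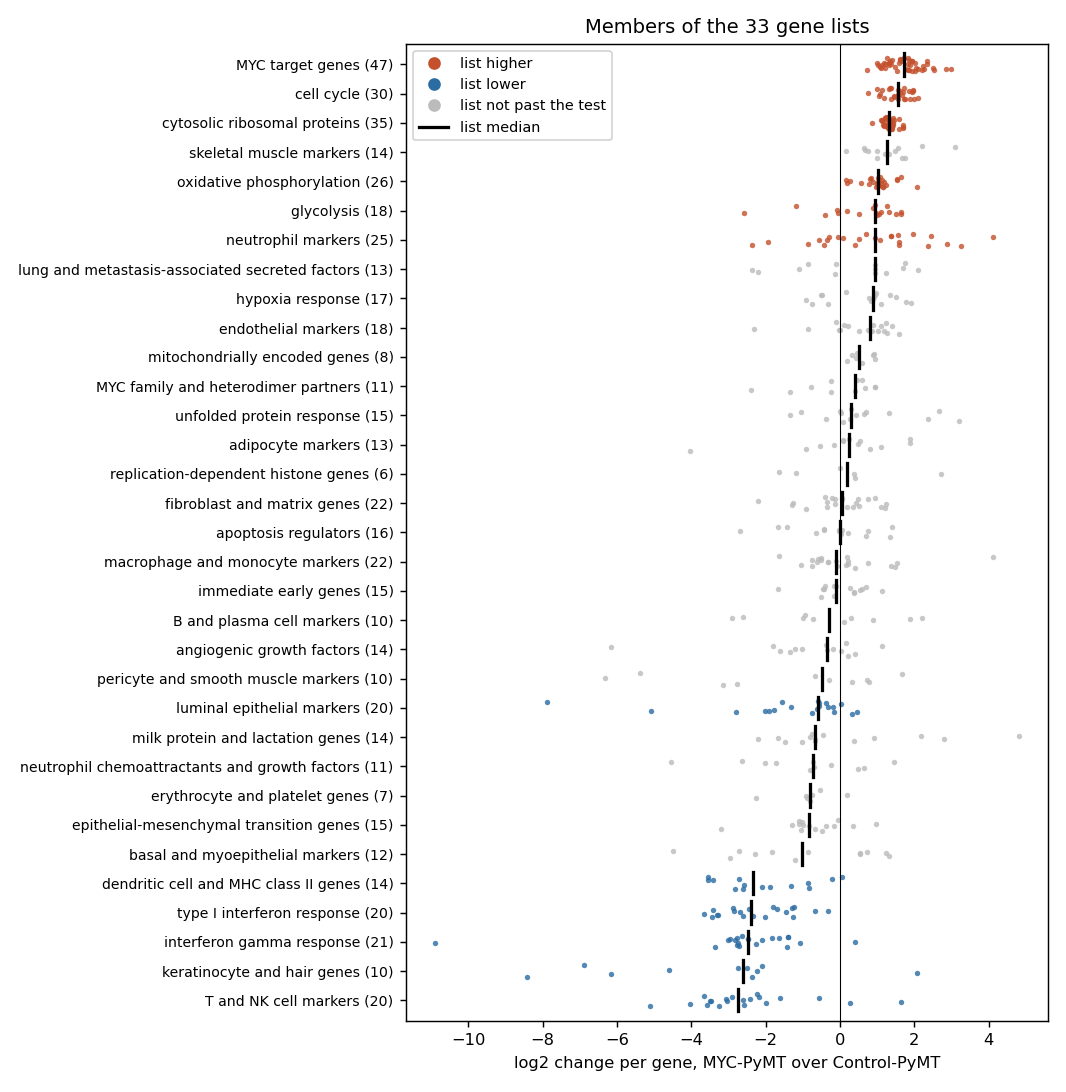
Log2 change in MYC-PyMT over Control-PyMT of each measured member of 33 gene lists, with the number measured in brackets; black bars are list medians, and orange, blue and grey mark lists called higher, lower or neither by camera. All 47 MYC target genes lie above 0, while the medians of both interferon lists are -2.48 and -2.40.

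The remaining 21 lists did not pass camera. Markers of other tissue compartments split. Endothelial markers rose in 9 of 18 cases and fell in 2 (median 0.79, adjusted p = 0.0582). Egfl7, a vascular gene, rose from 533 ± 124 to 1398 ± 368, and Vwf, von Willebrand factor, fell from 323 ± 108 to 62.0 ± 0.88. The Egfl7 call ended without Control-PyMT replicate 1 (log2 1.15, adjusted p = 0.0534). Macrophage and monocyte markers rose in 5 of 22 cases and fell in 5 (median -0.10, mean 0.14, test higher, adjusted p = 0.907); Cd68 rose from 816 ± 28.8 to 2124 ± 104. B and plasma cell markers rose in 2 of 10 cases and fell in 2 (adjusted p = 0.907), with Jchain up by 2.20 and Ighm at -2.60 on the log2 scale. Fibroblast and matrix genes rose in 4 of 22 cases and fell in 3 (adjusted p = 0.907; the median of 0.06 turned to -0.09 under upper-quartile scaling), and Dcn and Sparc fell, with log2 changes of -2.22 and -1.28. Pericyte and smooth muscle markers rose in 3 of 10 cases and fell in 4 (adjusted p = 0.170), with 1 rising under TMM or upper-quartile scaling. Cnn1 and Myh11, contractile genes shared with myoepithelium, fell from 4318 ± 214 to 55.3 ± 22.8 and from 5365 ± 1619 to 125 ± 6.32. Basal and myoepithelial markers rose in 2 of 12 cases, or 1 under TMM or upper-quartile scaling, and fell in 6 (adjusted p = 0.194); the oxytocin receptor gene Oxtr fell from 2242 ± 81.0 to 98.1 ± 5.04 and Lama3 from 730 ± 59.9 to 93.7 ± 22.9. Skeletal muscle markers rose in 4 of 14 cases (median 1.26, adjusted p = 0.0514). The list's mean log2 difference from all genes, 1.48, was 0.36 without Control-PyMT replicate 1 (adjusted p = 0.634) and 2.61 without Control-PyMT replicate 2. Among them Mb and Mylpf rose by 0.76 and 1.48, calls that ended without Control-PyMT replicate 1 (0.65, adjusted p = 0.0527, and 0.88, 0.220), without MYC-PyMT replicate 2 (0.77, 0.0680, and 1.03, 0.0725) and, for Mb, without MYC-PyMT replicate 1 (0.74, 0.0768). With the length trend removed neither passed (0.38 and 0.93, adjusted p = 0.157 and 0.117), nor with the length and GC trends removed (0.0653 and 0.108), nor did Mylpf without the variance trend (0.0611). Adipocyte markers rose in 4 of 13 cases and fell in 1 (adjusted p = 0.493). Lpl, lipoprotein lipase, rose from 1813 ± 194 to 6661 ± 708, and Lep, leptin, went from 96 reads to 3 (26.4-fold, interval 8.75 to 130.1). Erythrocyte and platelet genes fell in 1 of 7 cases (adjusted p = 0.339). Itga2b, an integrin of platelets, had a log2 change of -2.25, and Alas2, at -0.89, did not pass (adjusted p = 0.0926), although it did without MYC-PyMT replicate 1 (-1.37, 0.00375).

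Milk protein and lactation genes rose in 3 of 14 cases and fell in 6 (median -0.67, mean 0.10, test lower, camera adjusted p = 0.560). Wap, whey acidic protein, rose from 552 ± 194 to 3748 ± 47.0 and Csn1s1, alpha-S1 casein, from 2180.4 ± 702 to 9810.1 ± 2280.1. Angiogenic growth factors rose in 1 of 14 cases and fell in 6 (adjusted p = 0.152), among them Fgf1, from 4876 ± 289 to 67.5 ± 9.92, and Fgf2, from 782 ± 21.1 to 310 ± 23.1. Neutrophil chemoattractants and growth factors rose in 1 of 11 cases and fell in 5 (adjusted p = 0.152); Csf1 fell from 1515 ± 291 to 455 ± 45.2 and Il1b from 519 ± 267 to 76.9 ± 6.27. Lung and metastasis-associated secreted factors rose in 5 of 13 cases and fell in 4 (adjusted p = 0.493), with Angptl4 at 1.74 and Ptgs2 at -2.37. Epithelial-mesenchymal transition genes fell in 7 of 15 cases (adjusted p = 0.0533), including N-cadherin, Cdh2, with a log2 change of -3.21, and Tgfb2, from 1872 ± 203 to 938 ± 109. Hypoxia response genes rose in 8 of 17 cases and fell in 3 (adjusted p = 0.0991). Ak4 rose by 1.90 and Ddit4 by 1.76, the latter not without Control-PyMT replicate 2 (1.60, adjusted p = 0.0560). Unfolded protein response genes rose in 6 of 15 cases and fell in 2 (adjusted p = 0.120), led by Chac1, from 79.8 ± 2.28 to 744 ± 50.7, and Asns, asparagine synthetase, from 1943 ± 172 to 10036 ± 1657. Apoptosis regulators rose in 4 of 16 cases and fell in 3, or 5 under upper-quartile scaling (adjusted p = 0.902), and the survival genes Bcl2 and Bcl2l1 fell, with log2 changes of -2.69 and -1.43. MYC family and heterodimer partners rose in 4 of 11 cases and fell in 3 (median 0.40, mean -0.09, test higher, adjusted p = 0.902), with Mycl at -2.39 and the MYC antagonist Mxd4 at -1.35. Mitochondrially encoded genes rose in 2 of 8 cases (adjusted p = 0.0514), and the list's mean log2 difference from all genes, 0.75, was 0.33 with the length trend removed (0.481). These were mt-Nd6 (0.93) and mt-Nd1 (0.92), neither past the test with the length trend (0.389 and 0.124) or the length and GC trends removed (0.493 and 0.204), and mt-Nd1 not without any 1 of the 4 libraries (0.0559 to 0.126). Immediate early genes rose in 3 of 15 cases and fell in 1, or 0 and 2 under upper-quartile scaling (median -0.12, mean 0.0022, test higher, adjusted p = 0.907). Btg2 at 0.60 lost its call without either Control-PyMT library (0.0944 and 0.123) or MYC-PyMT replicate 1 (0.325), with upper-quartile scaling (0.0752) and without the variance trend (0.0890). Egr3 at -1.68 lost its call without Control-PyMT replicate 2 (-0.97, 0.140). Replication-dependent histone genes, whose messages lack poly(A) tails, rose in 1 of 6 cases and fell in 1 (adjusted p = 0.902), with Hist1h1b at 2.71 and Hist2h3c2 at -1.65, the latter not past the test without Control-PyMT replicate 2 (0.0523) or by DESeq2 (0.107).

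Adjusted over the list alone, counts among these 21 lists differed for 7. They were 3 higher for muscle, 10 higher for endothelium, 10 higher for hypoxia, 6 higher for metastasis-associated factors, 4 higher and 8 lower for milk, 0 higher and 0 lower for immediate early genes and 3 higher for fibroblasts. Which library was left out decided the call of 10 of these lists, given here as mean log2 differences from all genes with camera adjusted p. Adipocyte markers were at 1.00 without Control-PyMT replicate 2 (0.00659) and, with the sign turned, at -0.46 without Control-PyMT replicate 1 (0.350). The sign also turned for erythrocyte and platelet genes, at -1.54 without Control-PyMT replicate 1 (0.0105) and 0.16 without Control-PyMT replicate 2 (0.662). Neutrophil chemoattractants were at -1.24 without Control-PyMT replicate 2 (0.0184) and at -0.41 without Control-PyMT replicate 1 (0.350). Endothelial markers were at 0.90 without Control-PyMT replicate 2 (0.00659) and 0.78 without MYC-PyMT replicate 1 (0.0264), but at 0.39 without Control-PyMT replicate 1 (0.312). Skeletal muscle markers passed without Control-PyMT replicate 2 (0.000239) or MYC-PyMT replicate 1 (2.03, 0.000361), but were at 0.36 without Control-PyMT replicate 1 (0.634). Epithelial-mesenchymal transition genes were at -0.86 without Control-PyMT replicate 1 (0.0112) and -0.80 without MYC-PyMT replicate 2 (0.0204), but at -0.30 without Control-PyMT replicate 2 (0.208). Hypoxia genes were at 1.05 without MYC-PyMT replicate 1 (0.0041) and 0.46 without MYC-PyMT replicate 2 (0.272). Basal markers were at -1.21 without MYC-PyMT replicate 2 (0.0192) and -0.48 without MYC-PyMT replicate 1 (0.450). Pericyte markers were at -1.53 without MYC-PyMT replicate 2 (0.0473) and -1.13 without Control-PyMT replicate 2 (0.437). Mitochondrially encoded genes were at 0.89 without Control-PyMT replicate 1 (0.0263) and 0.61 without Control-PyMT replicate 2 (0.0889). The Control-PyMT libraries differed along GC content, with a Spearman correlation of 0.51 across genes between GC and replicate 2 minus replicate 1, against -0.01 between the MYC-PyMT libraries and 0.04 between the groups.

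**Figure D3:**
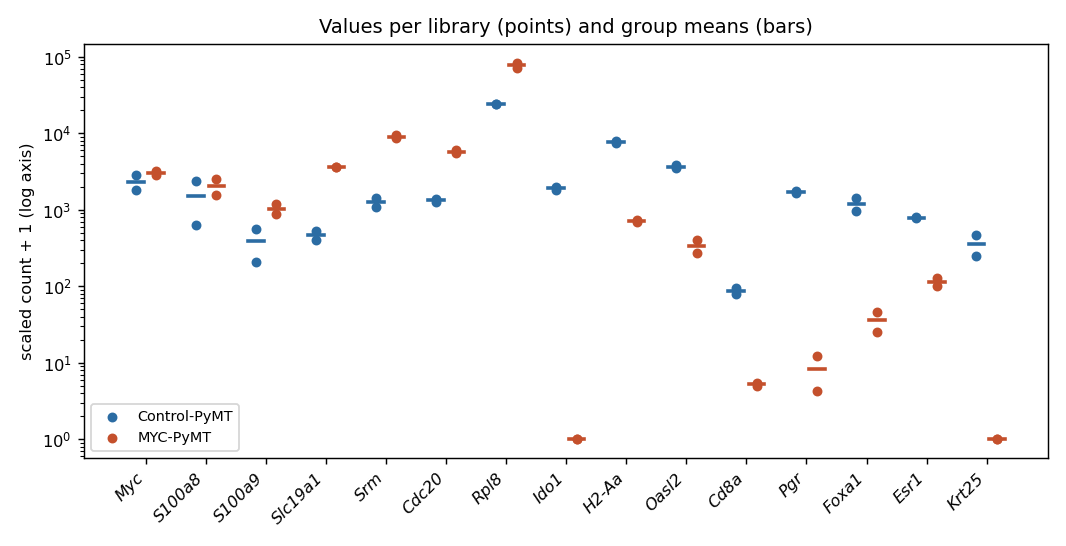
Scaled counts plus 1 on a log axis for 15 genes in each of 4 libraries (points) with group means (bars), Control-PyMT in blue and MYC-PyMT in orange. The groups overlap for Myc and S100a8 and lie apart for the other genes, down to no read of Ido1 or Krt25 in either MYC-PyMT library.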

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

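The removal of length trends, alone or with GC content, was chosen after the data had been seen, and the other alternatives before. Among genes called both as reported and under an alternative, 0 had the opposite direction in any alternative to the gene test. With all 4 libraries, the alternatives chosen beforehand called 6941 genes (without the variance trend) to 9393 genes (adjusted p under 0.10). EdgeR and DESeq2 on the recovered reads called 7925 and 7293, sharing 96.8% and 89.5% of the 8010 calls. Upper-quartile scaling moved the median log2 change of all genes from -0.02 to -0.16 and the share of higher calls from 48.6% to 39.8%. With the length trend removed 7591 genes changed, and 8595 with GC as well. Leaving out 1 library each gave 5236 to 6480 changed genes, 2663 to 3071 higher and 2573 to 3433 lower, sharing 62.4% to 76.5% of the calls. The library left alone in its group was assumed to vary like the others, and fewer samples enter these fits. In the simulation with 2 libraries per group, 8% of genes changed 1.5-fold and 92% of those changed 4-fold were recovered.

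With an estimated correlation, 0 lists changed, 0 higher and 0 lower by camera, against 12, 6 and 6 as reported, with 1 list at an unadjusted p under 0.05. For T and NK cell and luminal epithelial markers a higher correlation was not the cause. Their estimated correlations, -0.0083 and -0.017, lay below the preset 0.01. Their unadjusted camera p still went from 4.53e-07 to 0.0314 and from 0.000675 to 0.0656. With an estimated correlation camera takes its degrees of freedom from the residuals of 4 libraries, and at the preset one from the number of genes. That change applies to every list. The other called lists also had higher correlations, estimated at 0.12 to 0.71, and the causes of their loss were not separated. Fry passed 12 lists, 5 higher and 7 lower. It lost the glycolysis, neutrophil and keratinocyte lists and added angiogenic factors, pericytes and the unfolded protein response (0.0495 each). Leaving out 1 library gave 14 to 15 changed lists, 5 to 9 higher and 6 to 9 lower. MYC targets, cell cycle, ribosomal proteins, oxidative phosphorylation, both interferon lists, T and NK markers, MHC class II genes and luminal markers kept their calls under every alternative run but the estimated correlation. Skeletal muscle markers passed with a pseudocount of 5 (0.0412), no level filter (0.0381), upper-quartile scaling (0.0277) and lists without shared genes (0.0480). Endothelial markers passed with no level filter (0.0455) and with the length (0.0237) or length and GC trends (0.0142) removed. Mitochondrially encoded genes passed with no level filter (0.0110), TMM (0.0450) and lists without shared genes (0.0480), but not with the length (0.481) or length and GC trends (0.586) removed. Transition genes passed with a level filter of 50 (0.0455) and lists without shared genes (0.0480).

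The replicate number as a block gave 8039 changed genes, 3887 higher and 4152 lower, and 15 changed lists, 8 higher and 7 lower. S100a8 (adjusted p = 0.0364) and Alas2 (0.0238) passed under the block, as did the muscle (0.000262), endothelial (0.0405) and transition lists (0.0485). Deviations of same-numbered libraries correlated at -0.09 across genes, which are not independent replicates. No pairing showed across genes as a whole, but such a correlation cannot exclude a pairing that affects some genes.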

Other observations

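The gene lists and genes in the first paragraphs were chosen after the data had been seen, and so were the tests of explanations. The exception was the test of the Wnt target list, although its theme came from the data. Its members had not been looked at, apart from Lgr5, which was also on the basal and myoepithelial list. For the lists chosen after the data had been seen, the p-values are no independent evidence of a change.

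Genes for building blocks of growth were higher in MYC-PyMT. All 17 genes of serine, one-carbon and amino acid synthesis and uptake rose (median log2 2.09, camera adjusted p = 4.98e-09 over the 9 added lists, and adjusted p = 0.181 with an estimated correlation). The glutamine transporter gene Slc1a5 rose from 583 ± 93.8 to 6749 ± 332 scaled counts, Mthfd2, a mitochondrial folate enzyme, from 468 ± 65.2 to 4531 ± 51.8 and Phgdh, the first enzyme of serine synthesis, from 1116 ± 184 to 6750 ± 204. All 19 purine and pyrimidine synthesis genes rose (median 1.31, adjusted p = 8.46e-08, and adjusted p = 0.181 with an estimated correlation), among them Cad, from 718 ± 240.1 to 3113 ± 144. Cytosolic tRNA synthetase genes rose in 17 of 19 cases (median 1.00, adjusted p = 2.88e-06, and adjusted p = 0.181 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 9 of 19 cases and fell in 1, Scd1, a desaturase, from 78622 ± 24762 to 17234 ± 4151 (adjusted p = 0.0271, and adjusted p = 0.243 with an estimated correlation). Circadian clock genes rose in 3 of 15 cases and fell in 6 (adjusted p = 0.329).

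All 21 measured protocadherin beta genes, which lie in 1 cluster of cell adhesion genes, fell (median log2 -3.05, adjusted p = 1.37e-10, and adjusted p = 0.181 with an estimated correlation). Pcdhb17 fell from 507 ± 77.9 to 55.9 ± 6.45. Protocadherin gamma genes fell in 13 of 16 cases (adjusted p = 3.86e-06, and adjusted p = 0.181 with an estimated correlation), but these share 3′ exons, so their reads are uncertain. Igfbp5, an insulin-like growth factor binding protein and the most abundant gene of Control-PyMT replicate 2, fell from 307715 ± 19850 to 11974 ± 947. Caseins went apart: beta-casein (Csn2) rose from 690 ± 672 to 14194 ± 275 and kappa-casein (Csn3) fell from 300280.0 ± 693 to 95908 ± 23174. Scgb1b27 and Car6, secreted proteins of saliva and tears, rose from 7166 ± 4167 to 223205 and 77236 in MYC-PyMT replicates 1 and 2, and from 8636 ± 3797 to 74886 and 25142. Of 24 salivary and lacrimal gland genes written down without looking at their values, 7 were measured, of which 2 fell and 5 did not pass (adjusted p = 0.632). Pip, Lpo, Scgb1b27 and Car6, which rose, were not on that list. Most of its members were not measured, so it does not decide about gland tissue. Ccdc116 and Ydjc, which overlap on chromosome 16, rose by 4.27 and 4.47 on the log2 scale, and their neighbours 2610318N02Rik, Sdf2l1 and Ube2l3 by 3.49, 0.66 and 0.54. Processed pseudogenes had a median log2 change of 0.85, with 211 of 597 higher and 26 lower. As for Rps3a3, their reads may be split with the genes they derive from, so these values are uncertain.

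MYC target, cell cycle and ribosomal protein genes were higher in MYC-PyMT by camera at its preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.643, 0.691 and 0.741). A trend with transcript length was tested as a cause by removing it, and the mean log2 differences from all genes stayed at 1.86, 1.76 and 1.19. A larger share of neutrophils, the cells that S100a8-driven Cre marks, would bring S100a8 and S100a9 in excess of other transcripts. Gains of the 47 MYC target, 30 cell cycle and 35 ribosomal protein genes were the lowest MYC-PyMT minus the highest Control-PyMT library. But 67 of these genes gained more than 2850 scaled counts, the largest gain of both S100 genes together (highest MYC-PyMT minus lowest Control-PyMT library). The mean gain of both S100 genes was 0.0684% of the sum of the members' mean gains. The length trend therefore does not account for the whole rise, nor do neutrophils rich in S100a8 and S100a9 for those 67 genes. The comparison rests on both S100 genes and on absolute gains, which favour abundant members such as ribosomal protein genes. It did not count the 67 genes by list, so it does not show how many cell cycle genes they include. It cannot decide about neutrophils with little S100a8 and S100a9. A biological effect of the MYC genotype on tumour cells or other cells may remain and was not tested. The same holds for a difference between mice or batches that follows the groups.

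Interferon gamma and type I interferon response genes were lower in MYC-PyMT by camera at its preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.643 and 0.691). If fewer leukocytes of all kinds were the cause, these genes would fall no more than Ptprc. But their median log2 change lay below that of Ptprc by -1.38 (SE 0.31), and 37 of 41 genes fell further. That SE joins a resampling of the 41 genes (0.23) with the SE of Ptprc (0.21). The resampling treats genes as independent, although the lists had estimated correlations of 0.17 and 0.30, and does not measure the spread between libraries. Removing the length trend left a mean difference of -2.28 for both lists together. A loss of particular leukocytes such as the T and NK cells, whose markers fell with a median of -2.76, less interferon, or a direct effect on tumour cells could each contribute and were not told apart by a test.

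Of single hair inner root sheath genes, chosen after their values were seen, Krt73 fell from 1053 ± 413 to 0.549 ± 0.777 scaled counts, Krt71 from 213 ± 57.9 to 44.0 ± 12.4 and Tchh from 1646 ± 863 to 64.6 ± 1.18, while the call of the keratinocyte and hair list was lost with an estimated correlation (adjusted p = 0.907) and by fry (0.0610). Skin in the Control-PyMT pieces would bring the abundant epidermal transcripts, and the median of Krt1, Krt10, Lor, Flg and Krt2 was at most 0.057 of Krt73. That median rests on Lor, Flg and Krt2, while Krt1 stood at 0.579 and 0.328 of Krt73 in Control-PyMT replicates 1 and 2, Krt10 at 0.471 and 0.554 and Rptn at 1.36 and 0.408, so skin stays open. As a hypothesis, lower Wnt signalling may accompany these falls: of 12 measured Wnt target genes 9 fell, 1 rose (Lgr5) and 2 did not pass, with a mean log2 difference of -2.09 from all genes (adjusted p = 0.000469, and adjusted p = 0.181 with an estimated correlation). Axin2 had gone from 884 ± 16.6 to 15.4 ± 4.67, and no test separated Wnt signalling in tumour cells from hair follicles or from a different tumour type in each group.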
